A study of Nothobranchius furzeri with 3 samples.

How the data were processed

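Small RNA was sequenced from skin of the turquoise killifish, Nothobranchius furzeri, an annual fish with a short life span. The 3 samples came from males of the strain MZM-04/10p at an age of 39 weeks, per the labels. Libraries were prepared from total RNA with the Illumina TruSeq small RNA kit, per the labels' protocols. All samples belong to 1 group and are called libraries 1, 2 and 3 in accession order. The labels describe no second age, tissue or treatment, so no comparison between conditions was made. The sample titles carry different codes, but the labels do not state outright that each library came from a different fish, so the spread between libraries may be partly technical.

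The authors deposited a table of raw read counts, with whole numbers per miRNA name and 1 column per library, not normalized and not pooled. The submitters' processing notes name bcl2fastq 1.8.4, Trimmomatic 0.36, BWA 0.7.12-r1039 and SAMtools 1.3.1-9, without the role or settings of each. The genome build, the miRNA annotation, the number of mismatches allowed, the treatment of reads with several matches and the counting rule are not given in the sources used here. Of the 324 features, 235 carry a miRNA name and 89 only a prediction number, none with a 5p or 3p arm, and several names are those of whole families (let-7, lin-4, mir-8, mir-10), so reads of related miRNAs cannot be separated and each value is best read as that of a family or precursor. If reads with several matches were dropped or counted repeatedly, families with many genomic copies would be affected most. No genome sequence was used here, and 0 of the 324 names matched the gene table at hand, so no coordinates are given. A ligation-based small RNA library also captures some sequences better than others, so a ratio between 2 different miRNAs carries that bias. A ratio of 1 sequence between libraries does not, but a feature that pools related sequences may carry it where their mix differs. The labels mention no molecular identifiers, so reads may include PCR copies, and all intervals and limits cover counting error only.

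Library totals were 5021238, 8545292 and 9590428 counts for libraries 1, 2 and 3. A share of 1 library carries a 95% exact binomial (Clopper-Pearson) interval. A count of 0 allows up to 3 counts, equal to 0.597, 0.351 and 0.313 counts per 1000000 (CPM) in libraries 1, 2 and 3. CPM and percent shares were computed from the deposited counts with the library total as the denominator. Shares were left unscaled, also where they are compared between libraries, and values called TMM-scaled were scaled with edgeR's trimmed mean of M-values (TMM), whose factors were 0.94, 0.99 and 1.07.

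Before the data were examined, 23 lists of miRNAs were fixed by miRNA number: 11 for cell types or tissues and 12 for families or clusters. Lists for cell types covered epidermis, striated muscle, erythroid cells, leukocytes, endothelium, mesenchyme with smooth muscle, neural cells, sensory organs, pigment cells, liver with gut and endocrine tissue, and germline with embryo. Lists for families covered let-7, the miR-17-92 clusters, miR-15/16, miR-10 with miR-196, miR-99/100/125, miR-29, miR-30, miR-23/24/27, miR-26, miR-181, miR-21 and miR-101. No feature carried a number of the miR-99/100/125 list. The rule for named features, also fixed then, took the 20 features with the highest mean CPM, up to 4 members of each list with the highest mean CPM, and, among features with a mean count of at least 100, the 10 with the largest and the 5 with the smallest range between libraries. All other features named were chosen after their values were seen. A planned comparison of 5p and 3p arms was not possible, because the names carry no arm.

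For the 9 lists with at least 3 features, the mean log2(CPM + 1) of members was compared with that of all other features by a two-sided permutation test with 100000 resamples and Benjamini-Hochberg adjustment. Ratios of lists within a library were tested by an exact two-sided sign-flip permutation test over the 3 libraries, which cannot give a p below 0.25. The spread between libraries was estimated as the common biological coefficient of variation with edgeR 4.0.16 and an intercept-only design on the 158 features with a mean count of at least 10. A chi-square test of the 3 counts of each of these features, with Benjamini-Hochberg adjustment, asked whether they differed by more than counting error, and it compares these libraries, not conditions. Alternatives were other scalings (DESeq2 1.42.0 size factors, library totals), count filters, pseudocounts, families summed, the total without its most abundant feature, and each library left out in turn. Calculations used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

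The estimate of the coefficient of variation was tested on simulated data drawn at the means and totals of these 3 libraries. A true coefficient of variation of 0.3 was estimated as 0.29 on average, and one of 0.5 as 0.53. Every simulated feature had the same coefficient of variation, so the estimate was not tested where features differ in spread, as they do here. For the chi-square test, counts were drawn at the same means and the TMM-scaled library sizes, with counting error only. Errors of scaling and other spread between libraries were thus absent from these data. With nothing changed, the chi-square test called 0 of 1589 features over 10 runs. With 50 features changed in 1 library, it called 60.8% of those changed 1.2-fold, 81.0% of those changed 1.5-fold and 94.4% of those changed 2-fold. The permutation test reached an unadjusted p of 0.05 for 25 of 500 random lists of 5 features, a share that its design sets. Of 100 lists of 5 features raised by 6 on the log2 scale, 89 reached it. Shorter lists were not tried.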

Results

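The series describes the small RNA content of killifish skin at 39 weeks in 3 libraries from males of 1 strain, with no second group. The libraries held 5021238, 8545292 and 9590428 counts over all features. Of the 235 features with a miRNA name, 135 reached at least 10 counts in every library. Of all 324 features, 200 had at least 1 count in every library, and 58 had no count in any. Of the 89 features that carry only a prediction number (pred), 8 reached 10 counts in every library, and these 89 features together took 0.594% ± 0.0939 of counts (SD, n = 3). All errors below are SD over the 3 libraries unless stated.

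The skin profile was dominated by 4 features: mir-204, mir-26, mir-10 and mir-181. miR-204 is known from pigmented epithelia and other tissues, genes of miR-10 itself lie within the Hox clusters, and miR-26 genes lie in introns of CTDSP phosphatase genes. Their mean shares were 15.7% ± 3.69 for mir-204, 15.6% ± 2.14 for mir-26, 14.6% ± 4.05 for mir-10 and 11.3% ± 2.52 for mir-181. The first 3 means differed by less than their SDs, and a different feature led each library: mir-10 in library 1, mir-204 in library 2 and mir-26 in library 3. The fifth was mir-205, a miRNA enriched in stratified epithelium, at 6.63% ± 1.01, which was below each of the leading 4 in every library. These 4 features together held 57.2% ± 5.03 of counts, the leading 10 held 82.8% ± 2.38 and the leading 20 held 92.96% ± 0.435. Of the 10 most abundant features of each library, 9 were shared by all 3, and 15 features of the mean profile held 90% of counts.

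The next ranks held let-7, known for its role in developmental timing and differentiation, at 4.67% ± 2.34, mir-27 at 4.07% ± 0.164, mir-21, a miRNA raised in many states of injury, at 4.05% ± 1.06, and mir-22 at 4.02% ± 0.982. The means of mir-27, mir-21 and mir-22 could not be separated at this spread. They were followed by mir-455, whose host gene in vertebrates is the collagen gene COL27A1, at 2.15% ± 0.767, and by the feature named mir-337 at 1.73% ± 0.848. The other members of the leading 20 were mir-92 (1.55% ± 0.469), mir-199 (1.49% ± 0.643), mir-133 (1.47% ± 0.770), mir-30 (1.12% ± 0.118), lin-4 (1.05% ± 0.216), mir-101 (0.479% ± 0.202), mir-338 (0.462% ± 0.0994), mir-143 (0.421% ± 0.114) and mir-8 (0.406% ± 0.0949). lin-4 and mir-8 are the nematode and fly names of the miR-125 and miR-200 families.

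**Figure D1:**
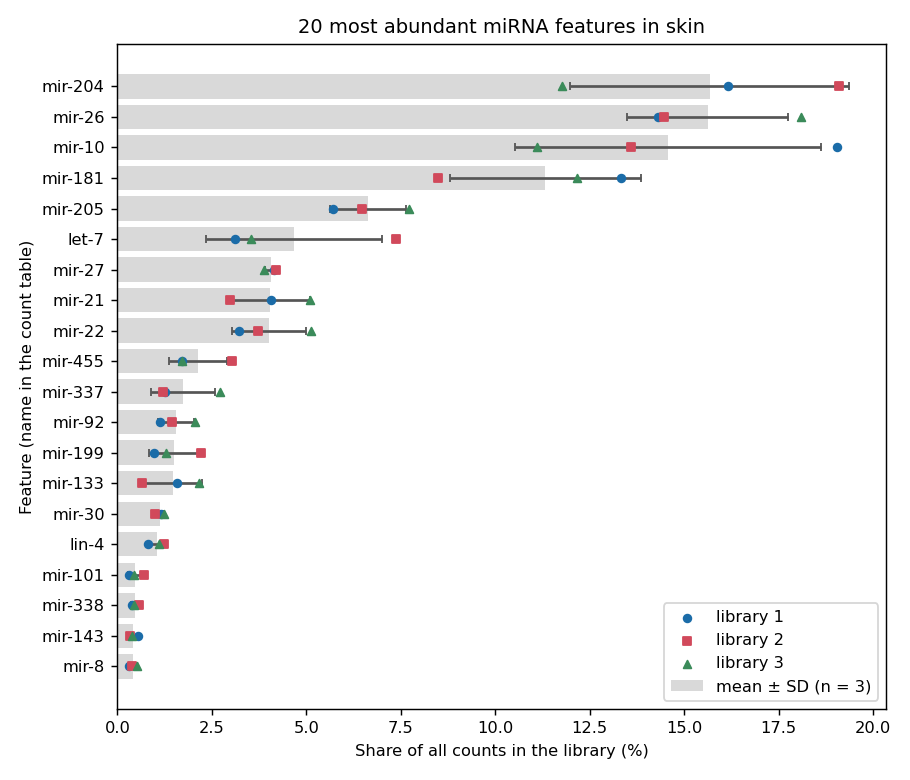
Share of all counts (percent, x axis) of the 20 most abundant features (y axis, names as in the count table). Bars give the mean and error bars the SD of 3 libraries, points give each library; the 4 leading features each hold over 11% on average, and mir-204, mir-26 and mir-10 overlap.

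Among the families fixed beforehand, the miR-23/24/27 cluster, which is co-transcribed, took 4.41% ± 0.177 of counts, of which mir-27 made up 92.2%, while mir-23 held 0.246% ± 0.0183 and mir-24 held 0.0986% ± 0.00545. The miR-17-92 clusters, known for roles in proliferation, took 2.11% ± 0.492, led by mir-92 (1.55% ± 0.469) over mir-25 (0.365% ± 0.0526), mir-17 (0.102% ± 0.0397) and mir-19 (0.0984% ± 0.0554). The miR-15/16 family took 0.394% ± 0.0556, with mir-16 at 0.255% ± 0.0276 and mir-15 at 0.139% ± 0.0308. mir-29, whose known targets include collagen transcripts, held 0.107% ± 0.0357. mir-196, whose genes lie within Hox clusters, held 0.0149% ± 0.00897. The feature mir-10 held 14.6% ± 4.05, but its name also stands for a family that includes miR-99 and miR-100, which lie outside those clusters. Families represented by 1 feature were let-7, mir-26, mir-181, mir-21, mir-30, mir-29 and mir-101. let-7 took 7.36% of library 2 (95% exact binomial interval 7.35 to 7.38) but 3.13% (3.11 to 3.14) of library 1 and 3.53% (3.52 to 3.54) of library 3.

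Of the lists for cell types, the pigment cell list, which here held mir-204 alone, took 15.7% ± 3.69 of counts, and the epidermis list took 6.99% ± 1.14. Since miR-204 is also known from other tissues, the share of the pigment cell list need not measure pigment cell content. Within the epidermis list mir-205 made up 94.9%, mir-203, a known regulator of keratinocyte differentiation, held 0.356% ± 0.139, and the feature named mir-200 had 0 counts in every library, which allows up to 0.597, 0.351 and 0.313 CPM in libraries 1, 2 and 3. With mir-8 added as the miR-200 family the epidermis list took 7.39% ± 1.23, an alternative chosen after the feature names were seen. Mesenchyme and smooth muscle miRNAs took 2.17% ± 0.467, led by mir-199 (1.49% ± 0.643), mir-143 (0.421% ± 0.114), mir-145 (0.207% ± 0.127) and mir-214 (0.0563% ± 0.00852). The endothelial mir-126 held 0.405% ± 0.0879. Leukocyte miRNAs took 0.479% ± 0.0210, with mir-146 at 0.251% ± 0.0836, mir-142 at 0.161% ± 0.0685, mir-223 at 0.0568% ± 0.0345 and mir-155 at 0.00941% ± 0.00228. The even total hid opposite changes, since mir-146 was lowest in library 2, where mir-142 and mir-223 were highest. Erythroid miRNAs took 0.130% ± 0.0886, as mir-451 (0.0973% ± 0.0748) and mir-144 (0.0327% ± 0.0147), with 0.226% in library 2, 0.113% in library 1 and 0.0509% in library 3, and a mean of 0.0821% without library 2. Without that library mir-451 held 0.0560% and mir-223 held 0.0369%, and without library 1 mir-145 held 0.135%.

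Striated muscle miRNAs took 1.51% ± 0.791 of counts, almost all as mir-133 (1.47% ± 0.770), with mir-1 at 0.0336% ± 0.0148 and mir-499 at 0.0118% ± 0.00631. Their share was 1.64% (95% interval 1.62 to 1.65) in library 1, 0.667% (0.662 to 0.673) in library 2 and 2.23% (2.22 to 2.24) in library 3. mir-133 had 45.2, 35.8 and 45.6 times the counts of mir-1 in libraries 1, 2 and 3, although both are co-transcribed. The share of this list thus rests on mir-133 and need not measure muscle content. The neural list took 0.224% ± 0.0695, with mir-128 at 0.177% ± 0.0655, mir-218 at 0.0199% ± 0.00117, mir-138 at 0.0152% ± 0.00202 and mir-9 at a mean of 0.00574%. The neuronal mir-124 had 19, 46 and 22 counts in libraries 1, 2 and 3. The sensory organ cluster took 0.107% ± 0.0198, as mir-182 (0.0891% ± 0.0139) and mir-183 (0.0177% ± 0.00637) with few counts of mir-96. The list named for liver, gut and endocrine tissue took 0.409% ± 0.257, of which mir-192 made up 89.7%. Its next members were mir-375, known from endocrine and secretory cells, at 0.0244% ± 0.0106, mir-194 at 0.00874% ± 0.00641, and the liver miRNA mir-122 at 0.00802% ± 0.00521, while mir-7 had 33, 85 and 70 counts and mir-122a/mir-3591 had 3, 3 and 16. Without library 3 mir-194 held 0.00545%, and without library 1 mir-122 held 0.00525%. The germline and embryo list held 0.0115% ± 0.0181, nearly all of it mir-202 in library 2, without which the mean was 0.0011%. The embryonic mir-430 had 1, 7 and 14 counts.

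**Figure D2:**
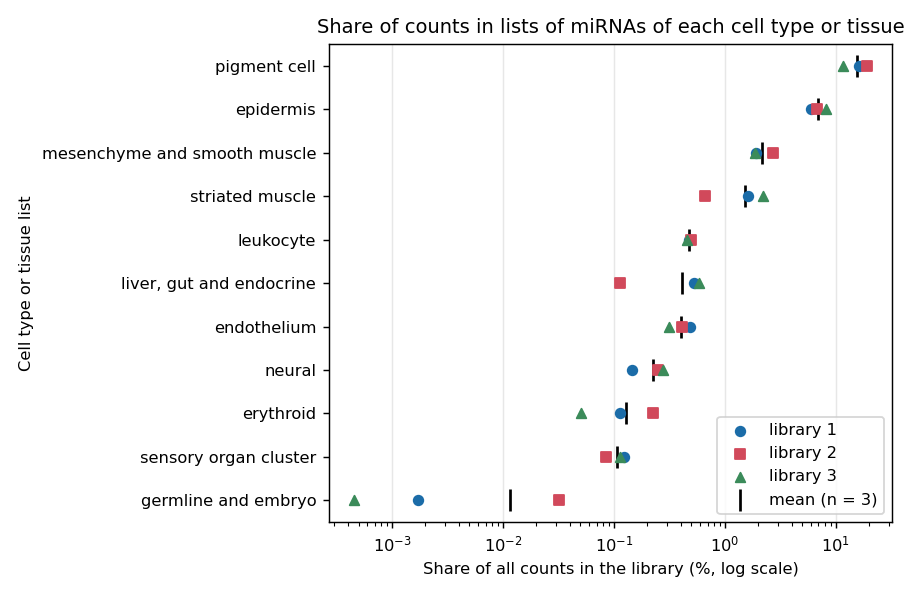
Share of all counts (percent, log x axis) in the lists of miRNAs of each cell type or tissue (y axis). Colored points give libraries 1, 2 and 3 and the black bar their mean; the leukocyte list lies within 0.460% to 0.502% in the 3 libraries, whereas the germline list spans 0.000459% to 0.0324%. Members of the leukocyte list changed in opposite directions between libraries. The pigment cell list holds mir-204 alone, which is also known from other tissues.

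Within each library the epidermis list exceeded the muscle, erythroid and leukocyte lists. The fold over striated muscle was 3.66, 10.1 and 3.68 in libraries 1, 2 and 3, a mean log2 ratio of 2.36 ± 0.844. The fold over erythroid miRNAs was 52.9, 29.9 and 162 (log2 5.99 ± 1.24), and over leukocyte miRNAs 12.6, 13.5 and 17.9 (log2 3.85 ± 0.269). Each direction was seen in 3 of 3 libraries, and the exact sign-flip test gave p = 0.25, the smallest it allows with n = 3, so none can pass 0.05. Without the leading feature of each list, mir-203 alone stood against the rest, at a log2 ratio of 3.03 ± 0.522 for muscle, 3.50 ± 1.26 for erythroid and 0.66 ± 0.952 for leukocyte miRNAs. The muscle ratio was thus higher than with all members and the other 2 lower, and the leukocyte ratio was not positive in every library. Without library 3 the erythroid log2 ratio was 5.31.

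Members of 6 of the 9 lists tested were more abundant than the other features of the table: the miR-23/24/27 cluster (log2 difference 8.69, adjusted p = 0.0123), the miR-17-92 clusters (7.89, 0.0123), mesenchyme (5.71, 0.0214), striated muscle (6.06, 0.0409), leukocytes (4.75, 0.0409) and epidermis (5.73, 0.0424), by permutation test with Benjamini-Hochberg adjustment. The neural list (2.02, adjusted p = 0.236), the gut, liver and endocrine list (2.40, 0.236) and the sensory list (1.55, 0.516) did not pass. With a pseudocount of 10 in place of 1, muscle and leukocytes no longer passed (both adjusted p = 0.0571, permutation test). This comparison is across miRNAs, which are not independent replicates. It also rests on the many features near 0: among features with a mean count of at least 10, 0 of 8 lists passed after adjustment by the same permutation test and 3 had an unadjusted p under 0.05, while the epidermis list, left with 2 features, was not tested.

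Over all 324 features the libraries ranked miRNAs alike but differed in level by more than counting error. Pearson's r of log2(CPM + 1) across the 324 features was 0.986, 0.992 and 0.986 for libraries 1 and 2, 1 and 3, and 2 and 3, and Spearman's rho was 0.952, 0.947 and 0.953, without p-values since features are not replicates. Of these features 58 had no count in any library, and shared zeros raise such agreement. Among features with a mean count of at least 10 the mean Pearson's r was 0.975, and rho was not computed. The common biological coefficient of variation was 0.456 with edgeR, and 0.371 without library 2. The chi-square test found 129 of the 158 features with a mean count of at least 10 to differ between libraries beyond counting error. By pairs, 109 differed between libraries 1 and 2, 107 between 1 and 3 and 121 between 2 and 3, which speaks only against a library having been deposited repeatedly. Among 115 features with a mean count of at least 100, the median ratio of the highest to the lowest library was 1.92 after TMM scaling, and the ratio exceeded 2 in 53 features, 4 in 15 and 10 in 3.

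The largest range belonged to mir-202. This miRNA, known from fish gonads, had 18.2, 326 and 2.91 TMM-scaled CPM in libraries 1, 2 and 3, from 86, 2758 and 30 counts. The feature named mir-716 had 279, 4182 and 945, and pred_770 had 35.2, 354 and 129. The erythroid mir-451 had 830, 1814 and 317. mir-192 and mir-194, co-transcribed in gut and liver, had 4987, 954 and 5004, and 89.2, 25.4 and 142.8. The other members of the 10 with the largest range were mir-676, with 16.95, 99.5 and 33.1, mir-360, with 3.81, 6.38 and 25.5, mir-299, with 593, 556 and 123.3, and pred_666, with 8.69, 43.1 and 25.6. Of these 10 features, 6 were highest in library 2, as were 48 of all 115 features with a mean count of at least 100. The steadiest features were mir-103, whose highest library exceeded its lowest 1.02-fold, mir-218 (1.03-fold), mir-3179 (1.09-fold), mir-130 (1.10-fold) and mir-883 (1.11-fold). Of the abundant features, mir-26 varied 1.15-fold, mir-205 1.18-fold and mir-27 1.22-fold, against 2.26-fold for let-7, 2.16-fold for mir-199 and 3.11-fold for mir-133.

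**Figure D3:**
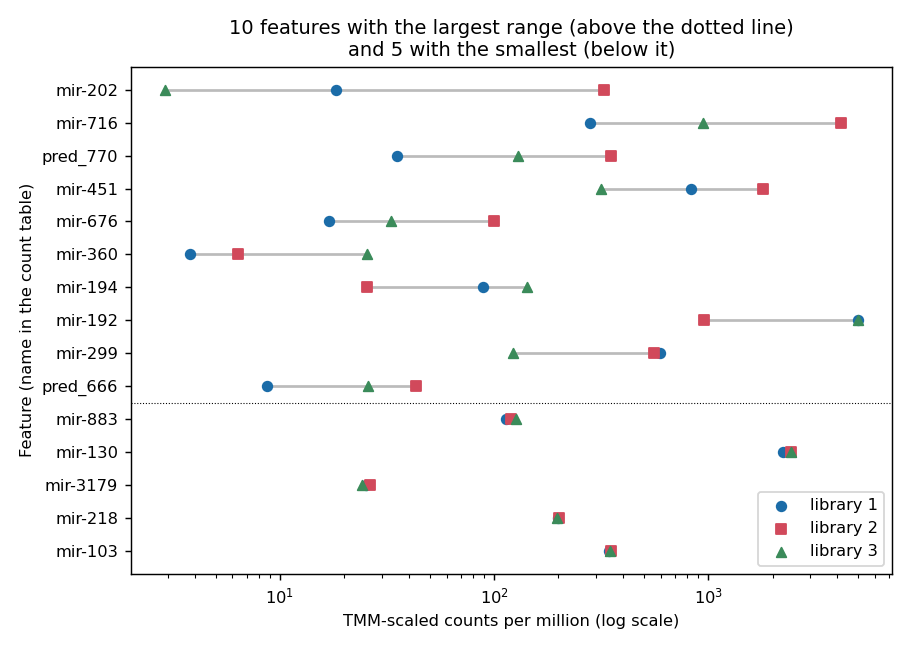
TMM-scaled counts per 1000000 (log x axis) of the 10 features with the largest range between libraries (above the dotted line) and the 5 with the smallest (below it), among 115 features with a mean count of at least 100. Points give libraries 1, 2 and 3 and gray lines their range; mir-202 spans 2.91 to 326, and the points of mir-103 lie on one another.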

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

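The alternatives were planned before the data were examined, except for the lists with family names added and the DESeq2 dispersion, which were chosen after seeing the data. No paired analysis was possible because all libraries belong to 1 group. The planned comparison of arms was not run, since names carry no arm. With the most abundant feature, mir-204, left out of the total, the epidermis share was 8.27% against 6.99%. Among features with a mean count of at least 10, lists that differed from the other features numbered 0 (of 8 tested, the epidermis list being too small to test) against 6 (of 9), and the log2 differences of the neural (-0.91), sensory (-2.02) and gut, liver and endocrine (-0.13) lists reversed, none having passed before; this filter removes the rare features that the lists were compared with. With a pseudocount of 10, 4 lists passed, muscle and leukocytes being lost (both adjusted p = 0.0571). The mean correlation between libraries was 0.975 with that filter against 0.988. The coefficient of variation was 0.301 as DESeq2's median over features, a different summary, and 0.371 to 0.482 with each library left out, lowest without library 2. Leaving out each library kept the counts of detected and of differing features within 1.5 times, and gave 6 lists throughout. The erythroid, gut and germline shares and the ratios to muscle and erythroid lists depend on library 2 or 3, as their values per library show. DESeq2 size factors or library totals gave coefficients of 0.452 and 0.462. Shares below about 1 CPM are near the limit of depth.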

Other observations

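Several features outside the lists add to the picture of this tissue. mir-140, a miRNA of cartilage, held 0.0572% ± 0.00544 of counts (SD, n = 3), alongside mir-455 at 2.15% ± 0.767. mir-184, known from corneal epithelium, held 0.321% ± 0.145, mir-425 held 0.336% ± 0.220 (0.210% without library 3), and mir-221 held 0.315% ± 0.110. mir-210, which responds to low oxygen in many cells, held 0.0251% ± 0.00525. The most abundant feature with only a prediction number, pred_586, held 0.386% ± 0.0974 and ranked 22 of 324, followed by pred_580 (0.0983% ± 0.0339) and pred_717 (0.0498% ± 0.0205).

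The table also lists features whose names are those of miRNAs of nematodes, insects, plants or herpesviruses, of which a set of 36 was chosen here after the names and counts had been seen. It leaves out let-7, lin-4 and mir-8, names from worm or fly that also stand for vertebrate families. Names known from other vertebrates were not counted either, so the set is no total of names unlikely in a fish. The 36 features took 0.301% ± 0.0720 of counts, of which the insect name mir-11 had 2503 ± 642 CPM. The 12 plant names took 0.0275% ± 0.00991 and the 3 herpesvirus names 0.00620% ± 0.00235, and 18 of the 36 had at least 10 counts in every library. Whether these reads come from killifish sequences that resemble those miRNAs was not tested, since the table holds no sequences.

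All tests in the next paragraphs were chosen after the counts had been seen, and with 3 libraries of 1 group no explanation by condition was testable. Differences between individual fish stay open throughout.

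mir-202 stood out in library 2, with 2758 counts against 86 and 30. Library depth or scaling is argued against, because after TMM scaling library 2 exceeded the other libraries together 42.1-fold (95% counting interval 35.0 to 51.2). Gonad tissue in library 2 could bring mir-202 and stays open. The other member of the germline and embryo list, the embryonic mir-430, had a ratio of 0.827 (0.285 to 2.16) from 1, 7 and 14 counts. An embryonic miRNA need not mark gonad tissue, so mir-430 cannot decide this, and its counts are also few. Reads passed over from another library of the same run were not tested.

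Muscle features were lowest in library 2. The unscaled muscle share was 2.45-fold (2.42 to 2.48) higher in library 1 than in the deeper library 2, while the deepest, library 3, held the most. The shares thus did not follow the order of library depth. A share is already divided by the library total, so this order is no real test of depth. Different amounts of muscle in the samples stay open: mir-133 and mir-499, which come from separate transcripts (mir-1 is co-transcribed with mir-133), both changed by at least 1.58 on the log2 scale between libraries 3 and 2, matched by a share of 0.0082 of 10000 random pairs of features. Adjusted over 6 lists this is 0.0492, too close to 0.05 to decide given resampling error, and the pattern had been noticed before it was tested. mir-1, left out of the pair, changed less, by 1.28 on the log2 scale between libraries 3 and 2. For the gut, liver and endocrine list the same test, over the 6 cell type lists that allow it, gave 0.643. The test scores the pair of libraries in which the smallest change of any member is largest. With mir-7 included this was library 1 over library 3, at -0.005 on the log2 scale, so a drop in library 2 was not tested. Different amounts of inner tissue stay open. There mir-192, mir-194, mir-375 and mir-122 were lowest in library 2, but mir-7 was not, at 1.44-fold (0.9497 to 2.22) of its level in library 1.

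Erythroid miRNAs went the other way, with an unscaled share 4.43-fold (4.30 to 4.58) higher in library 2 than in library 3. mir-451 and mir-144 are co-transcribed, yet their ratio was 3.91 in library 2 against 2.21 and 2.01 in libraries 1 and 3. If blood content differed, leukocyte miRNAs might follow, and the unscaled leukocyte share differed 1.09-fold (1.08 to 1.11) between libraries 2 and 3, or 1.18-fold after TMM scaling. Its members went both ways after TMM scaling, with mir-223 2.63-fold and mir-142 2.22-fold higher in library 2, and mir-146 at 0.581, mir-150 at 0.614 and mir-155 at 0.841 of their levels in library 3. Blood content cannot be told apart from other causes here, because members that go both ways do not decide it.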
